A study of Rattus norvegicus with 9 samples.

How the data were processed

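Expression was measured on 9 Affymetrix rat RAE230A arrays, 3 for each of the BSN, HRG and PTN media. The deposited values are GCOS signal intensities on a linear scale, where GCOS is the tool the labels name and its version and settings are not given in the sources used here. The trimmed mean signal of the arrays, leaving out 2% at each end, was 2500.48 to 2500.58, so the values appear on a common scale as deposited, and no further scaling was applied. The series design calls the arrays of a group biological replicates. With 3 arrays per group the number of arrays limits precision: the fit had 6 residual degrees of freedom, 12.7 after moderation.

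The table held 15923 probe sets, of which 57 controls were set aside and 15866 remained. A probe set was kept when its signal was above the array's 40th percentile on at least 3 of the 9 arrays, which left 10106. Gene names came from the platform's probe table: 12789 probe sets had 1 symbol, 312 had several and 2822 were not in that table. Symbols were updated from a rat gene table by Entrez ID for 12754 probe sets and by accession for 2, which changed 1 symbol. Of the kept probe sets 8415 had 1 symbol, for 7458 genes.

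Signals were transformed as log2 of the value plus 16, and every fold change in the text is on that scale, so it is smaller than the ratio of the mean signals where signals are low. Where a group's mean signal was below the mean of its arrays' 40th percentiles, the signals are given without a fold, since such a fold depends on the pseudocount. Linear models were fitted in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes with an intensity trend), with all 9 arrays in one fit. The comparisons were HRG against BSN, HRG against PTN, PTN against BSN, and HRG against the mean of the other groups. Adjusted p is limma's moderated t with the Benjamini-Hochberg method over all kept probe sets, and 0.05 was the threshold. Replicate numbers in the titles were checked for pairing by the correlation of arrays' deviations from their group means. For HRG and PTN all 3 pairs of arrays with one number were over 0.1 (0.118 to 0.332), which was taken as a hint of pairing from the data and not from the labels. These values were not set against other matchings of the arrays. The fit without the block was kept as planned, and the paired fit is given beside results whose call it changes. Array quality values were compared with exact permutation tests.

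Gene lists, 27 in number, were fixed before the data were examined, and the 24 with at least 4 kept genes were tested, which made 72 tests over 3 comparisons. Each gene entered by its probe set with the highest mean log2 signal. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over all list tests. Counts adjusted over the list alone use the Benjamini-Hochberg method among the list's members.

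Genes were named by a rule fixed beforehand. It took the 8 largest rises and 8 largest falls per pairwise comparison among probe sets with 1 symbol that passed, whose arrays did not overlap between groups and whose mean was above the median of the kept probe sets, passing over provisional names. It added up to 2 highest and 2 lowest members by moderated t of each list among those that passed, and 18 genes always named. Other members that complete a count of 5 or fewer were named after their values were seen, and their calls were not refitted with arrays left out one by one.

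The linear fit and camera at the preset correlation were tested on simulated data, drawn from the means and moderated variances of the kept probe sets, with changes planted in HRG. A planted log2 change of 1 was recovered for 88.1% of probe sets in HRG against BSN and in HRG against PTN, a change of 0.5 for 20.9% and 16.4%, and a change of 2 for 100% and 97%. Unchanged probe sets gave 9 and 11 calls, and PTN against BSN, where nothing was planted, gave 1. Of 2 planted list changes 2 were recovered, and of 70 other list tests none passed. Noise was drawn independently for each probe set, so the simulation cannot show false list calls that arise from correlated genes.

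Alternatives were quantile normalization, centring each array on its median, pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, no intensity trend, array weights, only the groups compared, the replicate number as a block, each array left out in turn, a 2-fold minimum, an adjusted p under 0.01, and for lists an estimated correlation, fry and the mean of a gene's probe sets. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.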

Results

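Ureteric buds were isolated from rat embryos at embryonic day 13, freed of the surrounding kidney mesenchyme, and grown for 4 days in a gel of 50% Matrigel and 50% collagen. The ureteric bud is the epithelial outgrowth that branches in the embryonic kidney to form the collecting duct system. All cultures received FGF1 at 250 ng/ml and GDNF, the ligand of the Ret receptor, at 125 ng/ml, and the groups differed in what was added to these factors. The BSN group received medium conditioned by a metanephric mesenchymal cell line. The HRG group received heregulin, a ligand of ErbB receptors, at 500 ng/ml. The PTN group received about 3 µg/ml of pleiotrophin, a heparin-binding growth factor, purified from that conditioned medium. RNA of 3 buds made 1 sample, and 3 samples per group were hybridised to 9 arrays. The series title counts BSN and PTN as branching cultures and HRG as non-branching growth. The description of the PTN samples calls them non-branching, so the labels disagree on PTN, and the groups here are named by medium alone. The array signals carry no morphology. No group received FGF1 and GDNF alone. A rise in a medium therefore cannot be told from a fall in the medium it is compared with.

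Pearson's r across probe sets of log2 signals was 0.946 to 0.979 between arrays of one group and 0.882 to 0.937 between arrays of different groups. PTN replicate 1 was the array least like the rest of its group, with a mean r of 0.946. The 3'/5' signal ratio of the actin control, which rises with degraded or 3'-weighted RNA, was 33.2 ± 4.91 in BSN, 25.2 ± 5.86 in HRG and 16.6 ± 1.4 in PTN (SD, n = 3). The exact two-sided permutation p was 0.2 for HRG against BSN and 0.1 for each comparison with PTN, where 0.1 is the smallest p that 3 against 3 can give. The GAPDH 3'/5' ratio was 4.57 ± 1.11 in BSN, 2.92 ± 0.802 in HRG and 5.14 ± 1.98 in PTN (SD, n = 3), with exact permutation p of 0.1 for HRG against BSN, 0.3 for HRG against PTN and 0.8 for PTN against BSN. The signal of the actin 3' control itself was 22019 ± 4415 in BSN, 13030 ± 1234 in HRG and 8267 ± 2298 in PTN, and all 3 exact permutation p were 0.1. Of these controls only the actin 3' signal separated the groups fully in all 3 comparisons. All of them, like every signal here, were measured on RNA amplified by 2 rounds of in vitro transcription.

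The first comparison asks how buds grown in heregulin differ from buds grown in conditioned medium. Ureteric bud tip genes were lower in heregulin, by unequal amounts. Ret, the GDNF receptor of the branching tip, had a signal of 13512 ± 1883 in BSN and 918 ± 171 in HRG (SD, n = 3), and it fell 14.5-fold (adjusted p = 1.8e-08). Cxcr4, a chemokine receptor, fell from 8227 ± 256 to 677 ± 77.2, and Gfra1, the co-receptor of Ret, fell 2.8-fold from 5916 ± 513 to 2113 ± 340. Further kept probe sets of these 3 genes fell as well. Ros1 and Tsc22d1 (1.42-fold), named after their values were seen, completed the 5 measured genes of the tip list, and all 5 passed as lower, against 4 after quantile normalization or median centring. The list fell against the other genes (camera, adjusted p = 3.96e-07), with adjusted p = 0.0539 with an estimated correlation.

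Genes that report FGF and ERK signalling fell beside the tip genes, although FGF1 was in every medium. All 6 measured members were lower in HRG, 5 after quantile normalization or median centring, and all 6 also passed when adjusted over the list alone. Mycn, a proto-oncogene transcription factor, fell 4.18-fold from 3120 ± 316 to 746 ± 181, and Spry1, a feedback inhibitor of receptor tyrosine kinases, fell 2.87-fold from 12757 ± 689 to 4448 ± 530 (SD, n = 3). Camera gave the list an adjusted p of 2.99e-06, with adjusted p = 0.0635 with an estimated correlation. Cell cycle genes also fell: of 27 measured members 19 were lower, none was higher and 8 did not pass, and adjusted over the list alone 22 were lower. Top2a, the topoisomerase of dividing cells, fell 2.42-fold from 8481 ± 770 to 3526 ± 648, and Ccnd1, encoding cyclin D1, fell 2.39-fold from 6383 ± 519 to 2661 ± 130. Camera gave this list an adjusted p of 4.43e-12, with adjusted p = 0.0539 with an estimated correlation. Cdkn1c, a cyclin-dependent kinase inhibitor from another list, fell 4.31-fold in the same arrays.

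Genes of the ureteric trunk and collecting duct went the other way. Of 11 measured members 4 rose, 1 fell and 6 did not pass, with the same counts when adjusted over the list alone. Aqp3, a basolateral water channel, rose from 524 ± 101 in BSN to 9668 ± 1570 in HRG, and Aqp4, a second basolateral water channel, rose 3.76-fold from 4656 ± 1513 to 16880 ± 1551 (SD, n = 3). A second, dimmer Aqp4 probe set did not pass (log2 change 0.48 ± 0.257 SE, adjusted p = 0.248). Scnn1b and Slc14a2, named after their values were seen, were the other members that rose, and Slc4a1 was the member that fell, a call lost after quantile normalization (adjusted p = 0.0526), with no filter (0.0783) and without BSN replicate 1 (0.127), BSN replicate 3 (0.156), HRG replicate 2 (0.086) or HRG replicate 3 (0.164). The trunk and collecting duct list had a camera adjusted p of 0.0202, with adjusted p = 0.356 with an estimated correlation, and 0.0512 without HRG replicate 1. Epithelial junction genes had 4 members that rose, 1 that fell and 9 that did not pass among 14. Cldn7, a tight junction claudin, rose 2.13-fold, Dsc2, a desmosomal cadherin, had a signal of 5108 ± 785 in BSN and 8351 ± 604 in HRG, and Gja1, the gap junction protein connexin 43, fell 5.34-fold from 10112 ± 804 to 1951 ± 657. Dsp and Pkp2, both desmosome genes named after their values were seen, were the other 2 that rose. The junction list passed at an adjusted p of 0.0358, with adjusted p = 0.183 with an estimated correlation. That call was lost without BSN replicate 2 (0.0618), HRG replicate 1 (0.0816) or HRG replicate 3 (0.0541), and after quantile normalization (0.0784), and the Dsc2 call was lost without BSN replicate 3 (0.0614) or HRG replicate 2 (0.0556).

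Large rises in heregulin were also measured for single genes, and what these genes share was not tested. Sprr1a, a cornified envelope protein of squamous and bladder epithelium, rose from 688 ± 188 to 21812 ± 5690. Tspan8, a tetraspanin membrane protein, rose 13.2-fold from 1280 ± 345 to 16826 ± 2337 (SD, n = 3). Ptprr, a receptor phosphatase that acts on MAP kinases, rose 6.47-fold, Vcam1, a cell adhesion molecule, 4.82-fold, Serpinb1a, a protease inhibitor, 4.46-fold and Cav1, the main caveolae protein, 4.22-fold. Tc2n, Tcim and Myzap rose 4.37-fold, 4.16-fold and 4.04-fold. Krt19, a simple epithelial keratin, rose 3.67-fold from 2925 ± 660 to 10622 ± 600. Other epithelial genes moved less: Krt8 was at 19710 ± 675 and 23543 ± 353 (adjusted p = 0.239), Krt18 at 28638 ± 1149 and 30231 ± 2289 (0.815) and Cdh1, encoding E-cadherin, at 11468 ± 2900 and 15372 ± 4124 (0.3). Of the 11 measured ureteric epithelial identity genes Krt19 rose, Lhx1, a transcription factor of the nephric duct, fell 2.56-fold and 9 did not pass. Erbb2, part of the heregulin receptor, was at 2699 ± 436 and 2755 ± 185 (adjusted p = 0.921), and of the 7 measured ErbB receptors and ligands none passed (camera adjusted p = 0.419), against 1 higher after quantile normalization.

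Among the largest falls were Crym, a thyroid hormone binding protein, which fell 15-fold from 29467 ± 7349 to 1950 ± 470, Olfm1, a secreted olfactomedin, 9.3-fold, and Cyth3, an exchange factor for Arf GTPases, 8.49-fold from 21196 ± 1949 to 2550 ± 761 (SD, n = 3). Tm4sf1 fell 7.78-fold, the noncoding RNA Lnc215 6.94-fold and Plpp3, a lipid phosphate phosphatase, 6.61-fold. Heparan sulfate proteoglycan and pleiotrophin-binding genes had 7 members that fell, 1 that rose and 7 that did not pass, and adjusted over the list alone 8 fell. Mdk, encoding midkine, the relative of pleiotrophin, fell 4.43-fold from 19009 ± 2345 to 4271 ± 508, and Ptn itself fell 3.77-fold from 3880 ± 964 to 1032 ± 355. Sdc4, a cell surface proteoglycan, was at 16882 ± 2333 and 25807 ± 1984, a call lost without BSN replicate 1 (0.0609), BSN replicate 3 (0.0582) or HRG replicate 3 (0.0649), and Sdc1, a second syndecan, was at 4444 ± 580 and 4311 ± 337 (adjusted p = 0.914). As a set these genes had a camera adjusted p of 0.00388, with adjusted p = 0.155 with an estimated correlation. Neural markers had 4 of 6 measured members lower, among them Dcx, a microtubule protein of migrating neurons, which fell from 988 ± 123 to 57.7 ± 22.6, and Map2, a dendritic microtubule protein, which fell from 3050 ± 433 to 611 ± 154. Elavl4 and Gap43, named after their values were seen, were the other 2. The list's camera adjusted p was 0.000653, with adjusted p = 0.111 with an estimated correlation. Cholesterol synthesis genes had 6 of 15 members higher and none lower, and 8 higher when adjusted over the list alone. Msmo1 and Nsdhl, both enzymes of the late pathway, were 1.59-fold and 1.69-fold higher in HRG. The Msmo1 call was lost without HRG replicate 3 (0.0567), and the Nsdhl call without BSN replicate 1 (0.0938), BSN replicate 3 (0.0773) or HRG replicate 3 (0.111). Camera gave this list an adjusted p of 0.00404, with adjusted p = 0.376 with an estimated correlation.

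Over all 10106 probe sets tested, 1594 differed between HRG and BSN at an adjusted p under 0.05, with 699 higher and 895 lower in HRG, or 802 higher and 778 lower after median centring, and 490 of them differed at least 2-fold. The count was 1053 without HRG replicate 3, and 2439 with array weights. Of 24 tested gene lists 8 passed, and none did with an estimated correlation.

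**Figure D1:**
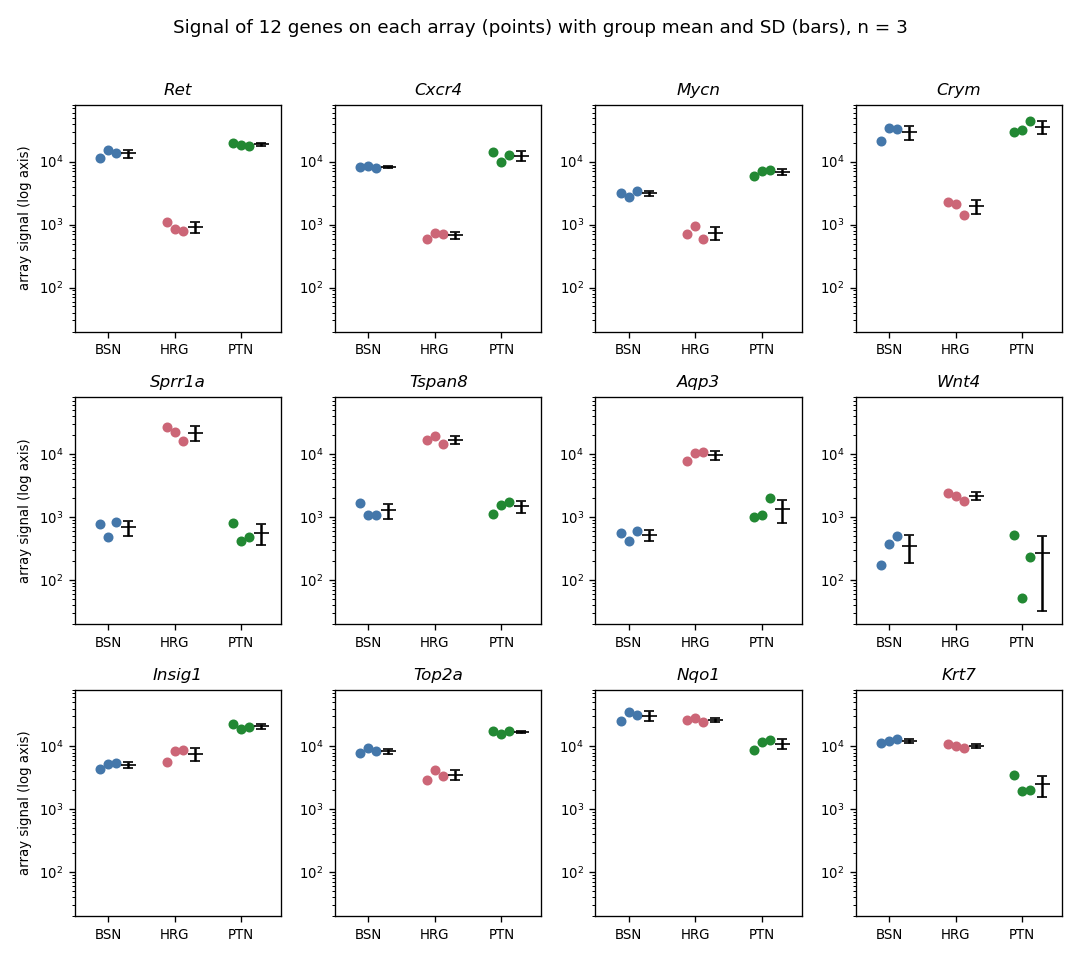
Signal of 12 genes on each of the 9 arrays, on a log axis, with points for arrays and black bars for the mean and SD of each group (n = 3). Ret, Cxcr4, Mycn and Crym were lowest in HRG, Sprr1a, Tspan8, Aqp3 and Wnt4 highest in HRG, and Insig1, Top2a, Nqo1 and Krt7 set PTN apart from BSN.

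The second comparison sets heregulin against pleiotrophin, both added as single factors to FGF1 and GDNF. Tip genes were again lower in HRG: 4 of 5 measured members fell, by unequal amounts. Ret was at 18756 ± 850 in PTN and 918 ± 171 in HRG, a 20.3-fold fall (SD, n = 3, adjusted p = 4.14e-09), Cxcr4 fell from 12304 ± 2230 to 677 ± 77.2 and Gfra1 fell 2.73-fold from 5771 ± 584, with Tsc22d1, named after its value was seen, as the fourth at 1.24-fold. The tip list had a camera adjusted p of 6.67e-06, with adjusted p = 0.0539 with an estimated correlation. Cell cycle genes fell in larger number than any other list: 23 of 27 were lower in HRG, none was higher, and 25 were lower when adjusted over the list alone. Top2a fell 4.84-fold from 16956 ± 861 in PTN, and Ccnd1 fell 2.91-fold from 7791 ± 802. As a set these genes had a camera adjusted p of 5.02e-17, with adjusted p = 0.0539 with an estimated correlation. FGF and ERK feedback genes had 4 of 6 members lower and none higher, and 5 lower when adjusted over the list alone, with Mycn down 9.2-fold from 6902 ± 791 and Spry1 3.26-fold from 14467 ± 386. Spry2 and Dusp6, named after their values were seen, were the other 2. The FGF and ERK feedback list had a camera adjusted p of 1.32e-05, with adjusted p = 0.0771 with an estimated correlation.

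Collecting duct genes split. Of 11 measured members 6 were higher in HRG, 1 was lower and 4 did not pass. Aqp3 rose 7.38-fold from 1348 ± 540 in PTN and Aqp4 3.56-fold from 4769 ± 856, while Aqp2, the apical water channel of principal cells, fell from 1531 ± 746 in PTN to 183 ± 30.7 in HRG (SD, n = 3). The list passed upward at a camera adjusted p of 0.0332, with adjusted p = 0.376 with an estimated correlation. That call was lost without HRG replicate 1 (0.0523) or PTN replicate 1 (0.0519), and with no filter (0.0621). Oxidative stress response genes had 9 of 12 members higher in HRG, 1 lower and 2 that did not pass. Nqo1, a quinone reductase controlled by Nrf2, was at 11114 ± 2087 in PTN and 26660 ± 1852 in HRG, and Gsta3, a glutathione transferase, was 2.41-fold higher. Mt2A, a metallothionein, fell 2.76-fold. The list's camera adjusted p was 0.00415, with adjusted p = 0.0963 with an estimated correlation. Cholesterol synthesis genes were lower in HRG than in PTN for 4 of 15 members and higher for none. Insig1, the sterol-responsive anchor of SREBP processing, fell 2.77-fold from 20783 ± 1824 to 7638 ± 1790 and Acat2 fell 1.71-fold, and Sqle and Fdps, the other 2, were named after their values were seen. Camera gave this list an adjusted p of 0.0203, with adjusted p = 0.484 with an estimated correlation, and 0.0633 without HRG replicate 1.

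Heparan sulfate proteoglycan and pleiotrophin-binding genes had 6 of 15 members lower and none higher when adjusted over all genes, and 6 lower and 1 higher when adjusted over the list alone. Ptn fell 4.01-fold from 4047 ± 301, Mdk 3.93-fold and Gpc2, a glypican, 2.19-fold. The proteoglycan list had a camera adjusted p of 0.0116, with adjusted p = 0.204 with an estimated correlation. Neural markers had 2 of 6 members lower, Dcx and Map2. The neural list passed at an adjusted p of 0.0316, with adjusted p = 0.284 with an estimated correlation, and missed the threshold without HRG replicate 3 (0.055) and with no filter (0.338). Simple epithelial keratins were higher in HRG than in PTN: Krt19 4.84-fold, Krt7 4.24-fold, Krt18 1.89-fold and Krt8 1.59-fold, and the epithelial identity list as a whole did not pass (5 higher, 1 lower, camera adjusted p = 0.0788). It did pass after quantile normalization (0.0373), without HRG replicate 1 (0.0482) and without PTN replicate 1 (0.0248), and by fry (0.00669). Junction genes had 8 of 14 members higher, including Dsc2 at 2.35-fold, and matrix protease genes 8 of 15, including Timp3 at 2.95-fold on one of its 2 probe sets, but neither list passed (camera adjusted p = 0.0813 and 0.055). Fry called the junction list (0.00136) and the matrix protease list (0.00194) higher in HRG. The junction list did pass after quantile normalization (0.0312) and without PTN replicate 3 (0.0322). The matrix protease list did pass with the paired fit (0.0476), after quantile normalization (0.0385, with 5 members higher), with no filter (0.0393), and without BSN replicate 1 (0.0493), HRG replicate 2 (0.041) or PTN replicate 1 (0.0473). H19, an imprinted noncoding RNA, rose 9.04-fold from 6324 ± 1614 in PTN to 56863 ± 11523 in HRG, Lgals3, encoding galectin 3, rose 8.13-fold, and Cyp1a1, a target of the aryl hydrocarbon receptor, 5.9-fold. S100a6 rose 5.63-fold. Tspan8 rose 11.4-fold, Tc2n 6.95-fold and Tcim 5.03-fold. Beside the tip genes, Crym fell 18.2-fold, Col9a1, a collagen chain, 12-fold from 21791 ± 968 to 1812 ± 276, Marchf11 8.14-fold, Rnase4 7.76-fold and Gja1 6.9-fold.

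Between HRG and PTN 2603 probe sets passed, 1423 higher and 1180 lower in HRG, and 748 of them differed at least 2-fold. With each array centred on its median the split was 1077 higher and 1418 lower, so the excess of higher calls depended on the scaling. Of 24 lists 8 passed, and none did with an estimated correlation.

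The third comparison asks how far purified pleiotrophin gave the expression state of whole conditioned medium. Tip genes were similar in signal: Gfra1 was at 5771 ± 584 in PTN and 5916 ± 513 in BSN (adjusted p = 0.885), and Ret was 1.4-fold higher in PTN at an adjusted p of 0.0424. That Ret call was lost after quantile normalization (adjusted p = 0.15), with no filter (0.055), with no intensity trend (0.0581), with the replicate number as a block (0.0519) and without BSN replicate 1 (0.16), BSN replicate 3 (0.0935), HRG replicate 2 (0.057), PTN replicate 1 (0.057), PTN replicate 2 (0.0867) or PTN replicate 3 (0.0771), and a second Ret probe set did not pass (0.999). Cxcr4 was 1.48-fold higher at an adjusted p of 0.0207, with neither of its other probe sets past the threshold, and the call was lost after quantile normalization (0.0707) and without BSN replicate 1 (0.0603), BSN replicate 3 (0.07) or PTN replicate 3 (0.0705). Of 5 tip genes these 2 passed and 3 did not, while after quantile normalization 0 were higher and 1 was lower, and the list as a whole did not pass (camera adjusted p = 0.525), with a median log2 change of -0.04, which was 0.09 after median centring, and a mean of 0.10.

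Cholesterol synthesis genes rose in pleiotrophin: 9 of 15 measured members were higher than in BSN and none was lower, with the same counts when adjusted over the list alone. Insig1 rose 4.12-fold from 5039 ± 567 to 20783 ± 1824 (SD, n = 3, adjusted p = 1.59e-05) and Fdps, which makes farnesyl pyrophosphate, 2.27-fold from 11345 ± 753 to 26333 ± 7223. As a set these genes had a camera adjusted p of 9.46e-07, with adjusted p = 0.146 with an estimated correlation. Cell cycle genes were higher for 7 of 27 members, lower for 1 and not past for 19, while 10 were higher after quantile normalization and 16 after median centring. Top2a rose 2-fold from 8481 ± 770 to 16956 ± 861 and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, 1.88-fold, while Ccnd2, encoding cyclin D2, was at 8414 ± 2943 in BSN and 4508 ± 1301 in PTN, a fall that did not pass after median centring (0.0703), with no filter (0.0712), with no intensity trend (0.056) or without BSN replicate 1 (0.15), BSN replicate 3 (0.0868) or PTN replicate 2 (0.134). The list's camera adjusted p was 1e-05, with adjusted p = 0.111 with an estimated correlation. Hypoxia and glycolysis genes had 5 of 17 members higher and none lower. P4ha1, a collagen prolyl hydroxylase, rose 2.62-fold and Ldha, a lactate dehydrogenase subunit, 1.98-fold from 14276 ± 1733 to 28711 ± 6832, and Eno1, Ndrg1 and Tpi1, named after their values were seen, were the others. That list passed at an adjusted p of 0.00537, with adjusted p = 0.597 with an estimated correlation, 0.103 by fry and 0.0564 without PTN replicate 1.

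Oxidative stress response genes fell in pleiotrophin. Of 12 measured members 7 were lower than in BSN and none was higher, and 9 were lower when adjusted over the list alone. Gstp1, a glutathione transferase, fell 4.08-fold from 15439 ± 1495 to 3843 ± 914 and Nqo1 2.79-fold from 30996 ± 5400 to 11114 ± 2087 (SD, n = 3). Camera gave this list an adjusted p of 0.000108, with adjusted p = 0.0539 with an estimated correlation. Matrix protease and inhibitor genes had 7 of 15 members lower and 1 higher. Mmp2, a gelatinase, fell 3.7-fold from 17665 ± 2186 to 4761 ± 508 on its brighter probe set, and its dimmer one did not pass (adjusted p = 0.317). Timp3, an inhibitor of such proteases, fell 2.42-fold on 1 of its 2 probe sets. Serpine2 was the member that was higher, at 1.7-fold, a call lost without BSN replicate 1 (0.0617), BSN replicate 2 (0.0746) or PTN replicate 3 (0.077). The matrix protease list had a camera adjusted p of 0.00425, with adjusted p = 0.0963 with an estimated correlation. TGF-beta and BMP pathway genes had 6 of 12 members lower and none higher. Id1, a BMP target, fell 3.55-fold from 4861 ± 317 to 1380 ± 311 and Fst, the activin antagonist follistatin, 3.03-fold. As a set these genes had a camera adjusted p of 0.0316, with adjusted p = 0.376 with an estimated correlation, and 0.0566 without BSN replicate 3. Under quantile normalization and under median centring 3 of its 12 members were lower in place of 6.

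Some keratins of simple epithelium were lower in pleiotrophin and Krt19 did not pass (adjusted p = 0.0827). Krt7 fell 5.06-fold from 12260 ± 1035 to 2500 ± 906 and Krt18 1.8-fold from 28638 ± 1149 to 16294 ± 4451 (SD, n = 3). Krt8 was at 19710 ± 675 and 15014 ± 2926, past the threshold at 0.0453 and not past it after median centring (0.136), with no filter (0.0739), with no intensity trend (0.0732), with only BSN and PTN in the fit (0.0886) or without BSN replicate 1 (0.0993), BSN replicate 2 (0.117), BSN replicate 3 (0.0975), HRG replicate 1 (0.0572), HRG replicate 2 (0.0655), HRG replicate 3 (0.0644), PTN replicate 2 (0.143) or PTN replicate 3 (0.157). With Cdh16, named after its value was seen, 4 of 11 epithelial identity genes were lower and none was higher, and Cdh1 was at 12040 ± 3133 against 11468 ± 2900 (adjusted p = 0.873). The list passed at an adjusted p of 0.0358, with adjusted p = 0.512 with an estimated correlation. It did not pass without BSN replicate 2 (0.0932), HRG replicate 1 (0.0509), PTN replicate 2 (0.0738) or PTN replicate 3 (0.0657). Among collecting duct genes Aqp2 rose from 139 ± 26.7, below the filter's percentile, to 1531 ± 746 and Aqp3 from 524 ± 101 to 1348 ± 540, Hsd11b2, which inactivates glucocorticoids, fell 2.78-fold, and 8 of 11 did not pass (camera adjusted p = 0.979). Egfr, the EGF receptor, fell from 924 ± 106 to 382 ± 111.

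Among brightly measured genes the largest rises in PTN over BSN after Insig1 were those of Rnase4 at 3.41-fold, Amot, a regulator of Hippo signalling, at 2.98-fold, Kcnj15, a potassium channel, at 2.94-fold and Tfrc, the transferrin receptor, at 2.72-fold from 9177 ± 536 to 25148 ± 3608 (SD, n = 3). A second probe set of Kcnj15 and of Tfrc did not pass. Ppp2r2b, Rassf3 and Lrig1, a negative regulator of ErbB receptors, rose 2.7-fold, 2.66-fold and 2.64-fold. Among brightly measured genes the largest falls were those of Cyth3 at 15.8-fold, H19 at 5.71-fold from 35547 ± 3073 to 6324 ± 1614, Bcat1, a branched-chain aminotransferase, at 5.48-fold, Krt7 at 5.06-fold, and Chac1, a glutathione-degrading enzyme induced by amino acid stress, at 4.31-fold. Plpp3, Gstp1 and Tmbim1 fell 4.13-fold, 4.08-fold and 3.71-fold. Second probe sets of Bcat1 and Plpp3 did not pass.

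Between PTN and BSN 2276 probe sets passed, 925 higher and 1351 lower in PTN, and 427 of them differed at least 2-fold. The median log2 change of all kept probe sets was -0.11, and with each array centred on its median the split was 1342 higher and 884 lower, so the direction of small changes depended on the scaling. The count was 1358 without BSN replicate 3 and 3480 with array weights. Of 24 lists 7 passed, and none did with an estimated correlation.

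**Figure D2:**
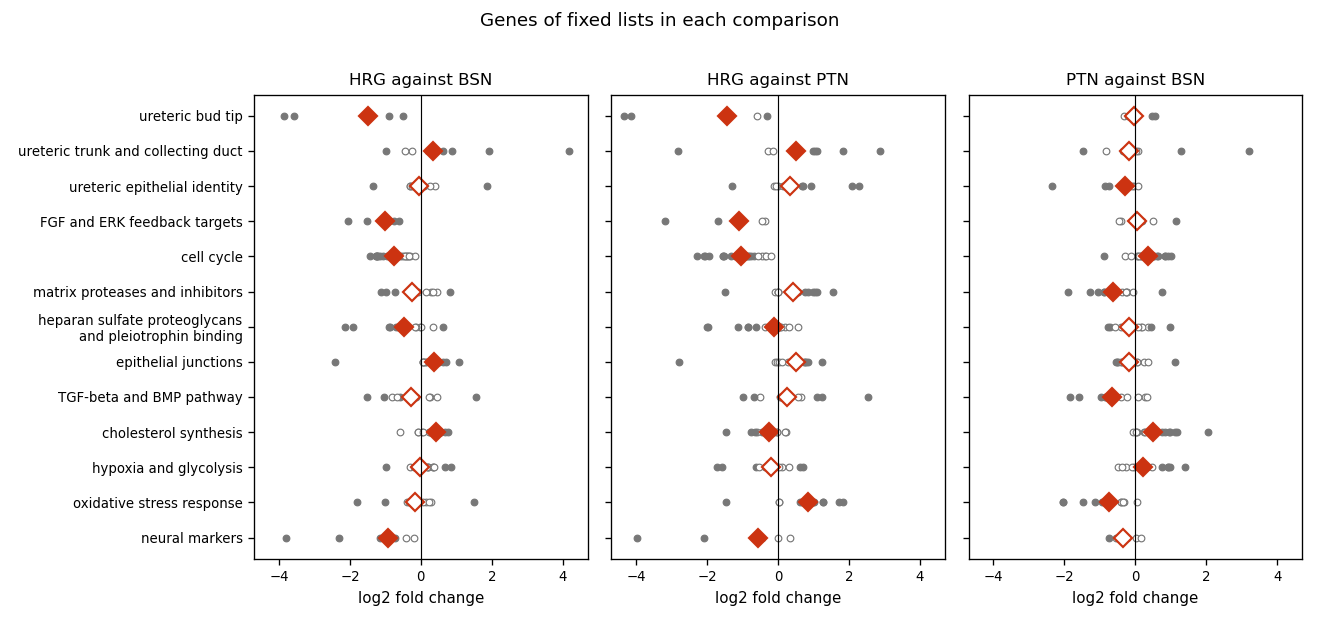
Log2 fold change of the measured members of the 13 gene lists that passed in at least 1 comparison, with a grey circle for each gene, filled where its adjusted p was under 0.05, and a red diamond for the list's median, filled where camera's adjusted p was under 0.05. Tip, FGF and ERK feedback and cell cycle genes lay left of 0 in both comparisons of HRG, and the tip median in PTN against BSN was -0.04, or 0.09 after median centring.

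Changes shared by both heregulin comparisons were counted next. In all, 877 probe sets passed in the same direction against BSN and against PTN, 418 higher and 459 lower in HRG, and 46 passed in opposite directions. Ret, Cxcr4, Gfra1, Mycn, Crym, Tcf7 and Lama4 fell and Sprr1a, Tspan8, Aqp3, Wnt4 and Krt19 rose in both. Tcf7, a transcription factor of the Wnt pathway, was at 5261 ± 294 in BSN, 432 ± 47.6 in HRG and 2227 ± 332 in PTN, Lama4, a laminin chain, at 2624 ± 396, 249 ± 196 and 4188 ± 650, and Wnt4, a Wnt ligand, at 349 ± 163, 2146 ± 313 and 263 ± 231 (SD, n = 3). Independent lists of these sizes would share 98.4 higher and 105 lower. In 100 simulations of unchanged groups against the same HRG arrays the mean number shared was 0. The correlation of the log2 changes across probe sets, which are not independent replicates, was 0.632 against 0.501 in the simulations, and the covariance was 0.2 against 0.0206. The simulated correlation comes from the use of the same simulated HRG arrays in both comparisons. Since the simulated groups did not differ at all, a shared count of about 0 and a small covariance were bound to follow. These values do not test whether the sharing exceeds that of 3 groups that all differ from each other. With 3 HRG arrays the group could not be split into parts of at least 2, so part of the excess may come from the shared arrays. Of the 877 probe sets, 210 also passed in PTN against BSN. Another 983 passed in HRG against PTN and in PTN against BSN but not in HRG against BSN. HRG was therefore not the only group that differed from both others. Heregulin against the mean of both other groups gave 1970 probe sets, 972 higher and 998 lower, of which 484 differed at least 2-fold, and the count was 1274 without HRG replicate 3.

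Lists that passed in one comparison but not in another also held single changes. In HRG against BSN Grem1, a BMP antagonist, rose 2.96-fold while Id1, Fst and Bambi fell (TGF-beta and BMP list, camera adjusted p = 0.495), Adamts1 rose and Mmp2, Mmp11 and Serpine2 fell (matrix proteases, 0.509), and Gstm1 rose while Gstp1 and Mt2A fell (oxidative stress, 0.63). A dimmer Mmp2 probe set did not pass there. Fry called the matrix protease list (0.0292) and the oxidative stress list (0.0439) lower in that comparison. In the hypoxia list Pfkfb3 and Ndrg1 rose and Eno1 fell (0.552), the Ndrg1 call being lost with no filter (0.0746), with no intensity trend (0.0656) and without BSN replicate 1 (0.172), BSN replicate 3 (0.088), HRG replicate 2 (0.158), HRG replicate 3 (0.156) or PTN replicate 2 (0.0516). In HRG against PTN Id1, Id2 and Grem1 rose and Bambi and Tgfbi fell (0.33), the Bambi call being lost with no filter (0.0587), with only HRG and PTN in the fit (0.0642) and without HRG replicate 2 (0.0538), HRG replicate 3 (0.109), PTN replicate 2 (0.0648) or PTN replicate 3 (0.0532) and the Tgfbi call without HRG replicate 3 (0.0779) or PTN replicate 2 (0.0724). Pfkp and Pfkfb3 rose and Ldha, Eno1 and P4ha1 fell in that comparison (0.0826), with 5 lower after median centring. That list did pass without PTN replicate 3 (0.0145) and with the mean of a gene's probe sets (0.031). The Pfkp call was lost after quantile normalization (0.0528), after median centring (0.0501), with no filter (0.0521) and without HRG replicate 1 (0.122), PTN replicate 1 (0.0506) or PTN replicate 3 (0.0654), and the Pfkfb3 call without HRG replicate 2 (0.0984), HRG replicate 3 (0.0736) or PTN replicate 3 (0.0906). In PTN against BSN Mycn rose 2.2-fold and no other FGF and ERK feedback gene passed (0.495). Sdc4 rose 1.96-fold with Gpc2, a call lost without BSN replicate 1 (0.0794), BSN replicate 2 (0.0635), BSN replicate 3 (0.0602), PTN replicate 2 (0.0561) or PTN replicate 3 (0.0914), while Ext1 and Ext2 fell, the Ext2 call being lost without BSN replicate 2 (0.0623) or PTN replicate 3 (0.0669), and the proteoglycan list did not pass (0.937). Cldn7 rose and Dsc2 and F11r fell among junction genes (0.868), with 0 lower after median centring. The F11r call was lost after median centring (0.0502), and the Dsc2 call after quantile normalization (0.0597), after median centring (0.123), with no filter (0.0633), with no intensity trend (0.0614), with only BSN and PTN in the fit (0.0826) and without BSN replicate 1 (0.148), BSN replicate 2 (0.122), HRG replicate 1 (0.0559), HRG replicate 2 (0.0602), HRG replicate 3 (0.0624), PTN replicate 2 (0.0528) or PTN replicate 3 (0.174). Fry called the TGF-beta and BMP list higher in HRG against PTN (0.0239) and the junction list lower in PTN against BSN (0.0345). Members outside the naming rule were named here after their values were seen.

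The remaining lists did not pass by camera in any comparison, and members that complete a count were named after their values were seen. Of 20 basement membrane and integrin genes Lama4, to a signal below the filter's percentile, Fn1, encoding fibronectin (2.14-fold), Lamb1 and Agrn fell and Col18a1 (2.19-fold) rose in HRG against BSN (adjusted p = 0.125). Against PTN Lama3, Col18a1 and Itga3 rose and Lama1, Lama4, Agrn and Fn1 fell (0.551). In PTN against BSN Lama1 rose, a call lost without BSN replicate 1 (0.0531) or BSN replicate 2 (0.0554), and Lama5 and Itga3 fell (0.751). Of 11 Wnt pathway genes Wnt4 and Myc rose and Tcf7 and Fzd1 fell in HRG against BSN (0.33), the Fzd1 call being lost without BSN replicate 1 (0.0995), BSN replicate 3 (0.0919), HRG replicate 1 (0.0883) or HRG replicate 2 (0.0744). Against PTN Wnt4, Fzd4 and Myc rose and Tcf7, Lgr5 and Fzd6 fell (0.314), with 5 lower after quantile normalization, and in PTN against BSN Lgr5 and Fzd6 rose and Tcf7, Fzd1 and Fzd4 fell (0.898). Fry called the Wnt list lower in HRG against BSN (adjusted p = 0.00488) and in HRG against PTN (0.0282).

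The unfolded protein response and p53 lists did not pass by camera, while fry called the former in HRG against PTN (0.0198) and in PTN against BSN (0.00488) and the latter in PTN against BSN (0.0154). Of 15 unfolded protein response genes Xbp1 rose, a call lost after quantile normalization (0.0746), with no filter (0.0565), with no intensity trend (0.0587) and without BSN replicate 1 (0.0944), BSN replicate 2 (0.136), BSN replicate 3 (0.0537), HRG replicate 1 (0.101), HRG replicate 2 (0.102) or HRG replicate 3 (0.0791), and Hsp90b1 and Pdia6 fell in HRG against BSN (adjusted p = 0.868). Against PTN Xbp1, Asns, Dnajb9 and Chac1 rose and Hsp90b1, Pdia4, Pdia6 and Creld2 fell (0.724). In PTN against BSN Pdia4, a call lost with no filter (0.0544), with array weights (0.0599) and without BSN replicate 3 (0.115), PTN replicate 1 (0.0529) or PTN replicate 3 (0.0927), and Creld2 rose, and Dnajb9, Chac1 and Asns, asparagine synthetase (3.64-fold), fell (0.551). Of 8 p53 and growth arrest genes Sesn1 rose and Cdkn1a and Cdkn1c fell in HRG against BSN (0.806). Cdkn1a, encoding the cell cycle inhibitor p21, was at 7184 ± 349 in BSN, 4331 ± 338 in HRG and 3031 ± 267 in PTN (SD, n = 3). Against PTN Cdkn1a, Mdm2 and Sesn1 rose and Cdkn1b and Cdkn1c fell (0.806), the Cdkn1b call being lost with only HRG and PTN in the fit (0.0555) and without HRG replicate 1 (0.0919), HRG replicate 2 (0.0604), HRG replicate 3 (0.0649), PTN replicate 2 (0.106) or PTN replicate 3 (0.0751). In PTN against BSN Cdkn1b rose, a call lost without BSN replicate 1 (0.0809), BSN replicate 2 (0.0503), BSN replicate 3 (0.0522), PTN replicate 2 (0.0889) or PTN replicate 3 (0.0661), and Cdkn1a and Ei24 fell (0.908), the Ei24 call being lost after median centring (0.0518).

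Of 9 interferon response genes Mx2 passed in HRG against BSN (adjusted p = 0.92), a call lost with no filter (0.0724) and without BSN replicate 2 (0.0669), BSN replicate 3 (0.126), HRG replicate 1 (0.0886) or HRG replicate 2 (0.132). Stat2, Mx2 and B2m, the light chain of class I MHC, were higher in HRG against PTN (0.0826), and B2m (2.62-fold) and Ifitm3 were lower in PTN against BSN (0.0826), the Ifitm3 call being lost after quantile normalization (0.117), after median centring (0.0805), with no filter (0.0756) and without BSN replicate 1 (0.0877), BSN replicate 3 (0.146), HRG replicate 1 (0.0513), PTN replicate 2 (0.0593) or PTN replicate 3 (0.127). The interferon list did pass in HRG against PTN without HRG replicate 3 (0.0456) or PTN replicate 2 (0.0468), and in PTN against BSN without PTN replicate 2 (0.0416) and with the mean of a gene's probe sets (0.0479). Fry called it higher in HRG against PTN (0.00488) and lower in PTN against BSN (0.00464). Of 10 immediate early genes Atf3 and Klf6 rose and Egr1, Ier2 and Egr2 fell in HRG against BSN (0.996). There the Atf3 call was lost with no filter (0.0902), with the 60th percentile filter (0.0529), with no intensity trend (0.0546), with the replicate number as a block (0.0543) and without BSN replicate 1 (0.0809), BSN replicate 2 (0.0565), BSN replicate 3 (0.185), HRG replicate 1 (0.164), HRG replicate 3 (0.125) or PTN replicate 3 (0.0567), and the Egr1 call with no filter (0.0629) and without BSN replicate 2 (0.105), BSN replicate 3 (0.112) or HRG replicate 1 (0.108). Against PTN Jun, Atf3 and Klf6 rose (0.751), with 1 lower after quantile normalization or median centring, and in PTN against BSN Ier2 and Egr2 fell (0.596), calls both lost without BSN replicate 3 (0.0544 and 0.0512), and Egr2 also after quantile normalization (0.0712). Of 9 solute transporters Atp1b1 and Fxyd4 rose, the latter call being lost without HRG replicate 3 (0.0501), and Slc12a2, the sodium-potassium-chloride cotransporter (1.93-fold), fell in HRG against BSN (0.419). Fxyd4 rose and Slc12a2 fell against PTN (0.937), and Slc12a2, Slc4a4 and Atp1b1 rose in PTN against BSN (0.205), where a second Atp1b1 probe set went the other way. ErbB receptors and ligands had Egfr alone past against PTN and in PTN against BSN (0.63 and 0.868), with 1 higher in the latter after quantile normalization. Fry called the ErbB list higher in HRG against PTN (0.0334). Fgfr2, an FGF receptor, was at 13472 ± 1480 in BSN, 18357 ± 1340 in HRG and 18190 ± 1910 in PTN (SD, n = 3), with adjusted p of 0.0332 and 0.0309 against BSN. A second Fgfr2 probe set did not pass, and the first call was lost with no filter (0.0512), with no intensity trend (0.059) and without BSN replicate 1 (0.13), BSN replicate 3 (0.0959), HRG replicate 1 (0.0557), HRG replicate 2 (0.0743) or HRG replicate 3 (0.14), the second after quantile normalization (0.128), with no intensity trend (0.0524), with only BSN and PTN in the fit (0.059) and without BSN replicate 1 (0.118), BSN replicate 3 (0.0905) or PTN replicate 3 (0.0937).

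Apart from neural markers, no list for another cell type passed by camera, while fry called stroma (0.0479) and blood (0.0292) markers lower in HRG against BSN and stroma markers lower in PTN against BSN (0.0479). Of 7 stroma markers Col5a2 (3.74-fold) and Vim fell in HRG against BSN (camera adjusted p = 0.399). The Vim call was lost after quantile normalization (0.0579), with no filter (0.0958), with no intensity trend (0.0615) and without BSN replicate 1 (0.144), BSN replicate 2 (0.144), HRG replicate 2 (0.0709), HRG replicate 3 (0.178) or PTN replicate 2 (0.0514). Sparc rose against PTN (0.863), and Sparc, a call lost without BSN replicate 3 (0.0678) or PTN replicate 3 (0.0664), and Col5a2 fell in PTN against BSN (0.413). Of 7 blood cell markers Coro1a, an actin-binding protein of leukocytes, fell in both HRG comparisons, with 879 ± 235 in BSN, 95.6 ± 30.5 in HRG and 1036 ± 164 in PTN (SD, n = 3), and Cd74 fell in PTN against BSN, a call lost after quantile normalization (0.0732), after median centring (0.0542), with no filter (0.0552), with only BSN and PTN in the fit (0.0564) and without BSN replicate 1 (0.0681), BSN replicate 3 (0.143), PTN replicate 2 (0.0528) or PTN replicate 3 (0.117). The list did not pass (0.362, 0.851 and 0.702 in the 3 comparisons). Of 4 nephron epithelium markers Lrp2, the endocytic receptor megalin, rose 3.37-fold and Synpo, an actin-associated protein of podocytes, fell 2.1-fold in HRG against BSN, and the list did not pass in any comparison (0.99, 0.898 and 0.92). Neural markers did not pass in PTN against BSN (0.539). In the lists with fewer than 4 kept genes, which were not tested, Crym was the mesenchyme marker that fell, Sprr1a the urothelial gene that rose and Kdr, the VEGF receptor of endothelium, fell from 742 ± 29.5 to 329 ± 27.6 in HRG against BSN. Gdnf, Erbb3 and Calb1 were below the filter and were not tested. Calb1, of the collecting duct list, was above the percentile on 2 arrays, at 829 ± 369 in BSN, 204 ± 99.8 in HRG and 415 ± 129 in PTN. Kcnj1 of that list, also untested, went the other way, at 29.6 ± 8.6 in BSN and 131 ± 119 in HRG. Wnt11, Etv4, Etv5 and Pax2 were not analysed here because no probe set carried their names.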

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

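Of 226 named gene results that passed, 183 stayed past under every refit, 43 lost the call under at least 1, and 0 changed sign. The refits changed scaling, pseudocount, filter, variance model, groups or block, or left out 1 array, the 60th percentile filter held 219 of the 242 named results, and the 2-fold minimum and stricter p were applied to counts alone. Array weights raised the count of probe sets to 2439 for HRG against BSN and 3480 for PTN against BSN, and the cause was not tested. A 2-fold minimum left 490, 748, 427 and 484 probe sets for HRG against BSN, HRG against PTN, PTN against BSN and HRG against the mean, and an adjusted p under 0.01 left 844, 1475, 1066 and 1126, since both thresholds are stricter. With an estimated correlation 0, 0 and 0 of the fixed lists passed in the pairwise comparisons, so their camera calls rest on the preset correlation, while fry called 13, 16 and 11. With 1 array left out the counts ran from 1053 to 2225, 1882 to 3109, 1358 to 3222 and 1274 to 2512, and the number shared in direction by both HRG comparisons from 611 to 1038. Lists past ran from 6 to 8, 7 to 10 and 6 to 7.

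With the replicate number as a replicate block the counts were 1641, 2690, 2362 and 2075, with 906 shared in direction, and 8, 9 and 7 lists passed. The deviations of arrays with the same number gave a hint of pairing for HRG and PTN only, and over all 9 such pairs 4 had r above 0.1, from -0.0970 to 0.332. In HRG against PTN the block brought the matrix protease list past (0.0476) and changed no other list or named gene call. In the other comparisons, where the arrays share only a number, Ret in PTN against BSN was at 0.0519 and Atf3 in HRG against BSN at 0.0543 under the block.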

Other observations

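The tests of technical causes and the 3 added gene lists in this part were chosen only after the results they concern were seen, except the splits of arrays in the last paragraph, which were planned. Fatty acid oxidation genes drew attention because Acadl, Acot1 and Eci3 were higher in HRG than in PTN. A list written then was first run with these 3 genes in it and afterwards without them, and the values here are without them. Of 17 genes 10 rose, 0 fell and 7 did not pass, with a median log2 change of 0.76, a camera adjusted p of 9.74e-06 and 0.0315 with an estimated correlation, adjusted over these 3 lists only. Hadh rose 2.20-fold, Eci2 2.15-fold, Decr1 1.90-fold and Cpt1a 1.77-fold. Amino acid response genes, prompted by Asns, Chac1 and Bcat1, did not pass in PTN against BSN (21 genes, adjusted p = 0.162), and neither did imprinted growth genes, prompted by H19, Igf2 and Cdkn1c (8 genes, adjusted p = 0.828).

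In the fit of all groups together, PTN against BSN gave 1.43 times as many probe sets as HRG against BSN. The median size of log2 change was 0.291 against 0.226. Fewer probe sets differed at least 2-fold, 427 against 490, and the root mean square change was below the 0.528 of HRG against BSN. After quantile normalization the ratio was 1.21, and with 1 array left out it then ran from 0.899 to 1.58. Median centring kept the order, with 2226 probe sets for PTN against BSN and 1580 for HRG against BSN. Scaling stays open as a cause, since the ratio fell below 1 under quantile normalization only with an array left out as well. Without PTN replicate 1 the ratio was 1.45, with 3222 probe sets for PTN against BSN and 2225 for HRG against BSN. Both counts rose, even that of HRG against BSN, which holds no PTN array, because the groups share 1 estimate of variance. The ratio therefore cannot show whether that array was the cause. On the deposited values the lowest ratio with 1 array left out was 1.03. With only the groups compared in each fit the order was reversed, with 1804 probe sets for PTN against BSN and 2138 for HRG against BSN. The excess in PTN against BSN therefore depended on fitting all groups together. RNA integrity stays open, because the exact permutation p of the actin ratio was 0.1, the smallest possible, while that of GAPDH was 0.8. No biological explanation was tested.

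Coro1a, Dcx and Map2 fell in HRG to signals below the filter's percentile, which could come from other cells left on the buds in BSN. The median log2 change of 6 other blood markers was -0.10, but 0 of them lay 2-fold above that percentile in BSN, so blood cells stay open. For 4 other neural markers the median was -0.58, with 2 of them 2-fold above it, so neural cells stay open too. For Crym, the only other kept mesenchyme marker changed by 0.95. It did not lie 2-fold above that percentile in BSN, and 1 marker cannot decide. Wt1, Gdnf, Itga8 and Tmem100, the mesenchyme markers below the filter, were not above the percentile on any array. In BSN the brighter Wt1 probe set was at 418, Gdnf at 83.8, Itga8 at 271 and Tmem100 at 404. They gave no sign of mesenchyme in BSN, but whether these probe sets would detect it was not tested, so mesenchyme stays open. Coro1a, Dcx, Map2 and Crym also fell in HRG against PTN. Crym was at 21064 to 34694 on the BSN arrays and at 29769 to 44714 on the PTN arrays. To account for both falls, such cells would have to be left on the PTN buds as well. No biological explanation was tested.

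The 10 splits of 6 arrays are too few for a test of the counts: 1 split, the real one, reached the real count of 1594 for HRG against BSN, where the highest other gave 0, 1 reached 2603 for HRG against PTN, where the highest other gave 1, and 1 reached 2276 for PTN against BSN, where the highest other gave 0. For HRG against the mean 2 of 100 drawn partitions of the 840 reached the real count of 1970, the other being the PTN arrays against the rest with 2797.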
